A study of Mus musculus with 45 samples.

How the data were processed

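RNA of inflammatory monocytes (iMo), interstitial macrophages (IM) and alveolar macrophages (AM), sorted by flow cytometry from lungs of C57BL/6J mice, was sequenced by the authors from low input with a Smart-seq2 type protocol. Per the labels, the 45 libraries fall into 21 groups: each cell type at 0h, and at 2, 6 and 20h after intraperitoneal (ip) or intranasal lipopolysaccharide (LPS). The series text gives 22h where the sample labels give 20h, and the labels were used. Titles end in a letter and a 6-digit code. Code 171227 holds the IM and iMo libraries of 0h, 3 of the 4 AM libraries of 0h and all nasal libraries, and codes 160623 and 161219 hold the ip libraries, so that AM 0h 160623 alone joins 0h to the codes of ip. Code 160623, whose titles carry no letter, is written N160623 in the results. The labels do not say whether replicates are separate animals, and p-values measure the spread between these samples.

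The deposited table gives TPM for 23594 gene rows, computed by the authors. The submitters' processing notes name STAR, HOMER and mm10; versions and the gene annotation are not given in the sources used here. Read depth is not kept in TPM, so precision was judged from replicates: Pearson r of log2(TPM+1) within groups of 0h and ip ran from 0.936 to 0.981. Column sums of the 0h and ip libraries ran from 331473 to 551635 TPM, and 4068 to 7298 genes had at least 5 TPM. Rn45s, a ribosomal RNA precursor, held 4.33 to 33.32% of the column sums, with a median of 29.57% in code 160623, 11.945% in 161219 and 6.27% in 171227. No 2 columns were identical.

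The row names were checked against the values before any gene was read. They did not match in the 18 nasal columns (see the results), so no gene was taken from these, and the planned nasal comparisons, route comparisons and nasal interactions were not run; only the number of rows that differ between nasal times is given. The fit used the 27 libraries and 12 groups of 0h and ip.

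TPM values were put on a log2 scale after adding 1 TPM, and 8937 genes with at least 5 TPM in at least 2 libraries were tested. In R 4.3.3 with limma 3.58.1, 1 linear model with a coefficient per group was fitted over the 3 cell types, with empirical Bayes moderation allowing a mean-variance trend. Contrasts were the pairs of cell types at 0h, each ip time against 0h and 20h against 2h within each cell type, and differences of the ip responses between cell types over the 3 times (moderated F test). P-values are from limma's moderated t and F tests with Benjamini-Hochberg adjustment within each contrast, and genes with an adjusted p under 0.05 were called. Contrasts against 0h within a cell type share their 0h libraries, and no overlap between them is reported. Fold changes of log2(TPM+1) understate changes of low genes, and a gene listed at 0 TPM in all libraries of a group is given without a fold.

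Before the data were examined, 27 gene lists were fixed: 12 of cell type markers (alveolar macrophage, interstitial macrophage, classical monocyte, nonclassical monocyte, neutrophil, eosinophil, dendritic cell, lymphocyte, lung epithelial, endothelial, fibroblast and erythroid) and 15 of responses (immediate early, proinflammatory cytokines and enzymes, chemokines, NF-kB pathway and feedback, type I interferon-stimulated, interferon-gamma-associated, MHC class II, anti-inflammatory and feedback, TLR4 pathway, cholesterol synthesis, LXR and lipid efflux, cell cycle, glycolysis, oxidative phosphorylation and lineage transcription factors). Member counts use the adjustment over all tested genes, and again over the list alone. Camera of limma tested each list with 2 members or more with a preset correlation between genes of 0.01 and with an estimated one. Of 375 pairs of list and contrast, camera called 194 with the preset correlation and 47 with the estimated one. Median, mean and test of a list differed in sign in 70 pairs, 6 of them called: chemokines in AM at 20h, classical monocyte markers and immediate early genes in IM at 2h, immediate early and cell cycle genes in IM at 6h, and cell cycle genes in AM at 20h against 2h.

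Named genes followed a rule. List members are examples if among the 2 to 4 of largest absolute fold change of those called; where none was called, the largest is given as a value. For each contrast, the genes of largest change in each direction were named among those called, with libraries that do not overlap and a mean of at least 10 TPM in the higher group: 5 for the 0h pairs and the 6h contrasts, 3 for the others. For each F test the 6 genes of smallest p with at least 10 TPM in a group were named. Gene models (Gm and a number, Rik, Mir, Snor, LOC) were passed over, and some genes the rule reaches are left out.

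The model was tested on simulated data of 8937 genes, of which 200 were changed by 2, 4 or 8 times. It recovered 1, 85 and 95% of them for IM against AM at 0h, 19.5, 94 and 97% for AM at 6h, 1.5, 76 and 94.5% for IM at 2h and 2, 76 and 95% for iMo at 2h, with at most 14 false calls.

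The alternatives planned were a pseudocount of 0.1 TPM, no filter, quantile normalization, array weights, the title code as a covariate, a block on the letter and code of the titles, a fit within each cell type, code 171227 alone for the 0h pairs, and leaving out each library in turn, where a lone remaining library is assumed to vary like the other groups. Chosen after seeing the data were a fit with all 45 libraries, a fit without code 160623, which makes the same assumption, rescaling without Rn45s and Lars2, and a neutrophil score as a covariate, and for iMo against IM after ip LPS the title code and leaving out each library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and gene positions were taken from GENCODE M21.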

Results

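The libraries measured messenger RNA of iMo, IM and AM before (0h) and 2, 6 and 20h after LPS, the bacterial product sensed through TLR4. Of the 45 libraries, 8 were taken at 0h, 19 after ip and 18 after nasal LPS. The 27 of 0h and ip formed 12 groups. AM had 4 libraries at 0h, 2 at 2h, 3 at 6h and 2 at 20h after ip LPS, and each IM and iMo group had 2. TPM values carry no read depth. Each log2 fold change below is given relative to the median of all 8937 genes tested in its comparison, and that median is printed beside the count. The tests, and the words rose and fell, refer to the values before this subtraction. The log2(TPM+1) scale understates changes of low genes.

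The row names of the table did not match the values of the 18 nasal columns. Across rows, log2(TPM+1) of nasal libraries correlated with that of 0h and ip libraries at a Pearson r of 0.01 to 0.025 (median 0.015), against 0.757 to 0.989 among the 0h and ip libraries and 0.873 to 0.991 among the nasal libraries themselves. Actb, the cytoskeletal actin, had a median of 3721 TPM in the 0h and ip libraries and 0 in the nasal ones. Lyz2, the lysozyme of myeloid cells, had 10907 TPM against 0. In 58 windows of 400 rows, the best correlation over shifts of up to 100 rows had a median of 0.3, above the 0.185 that was the highest with shuffled rows in 58 of 58 windows, and the median at no shift was 0.002. No gene was therefore read from the nasal columns.

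**Figure D1:**
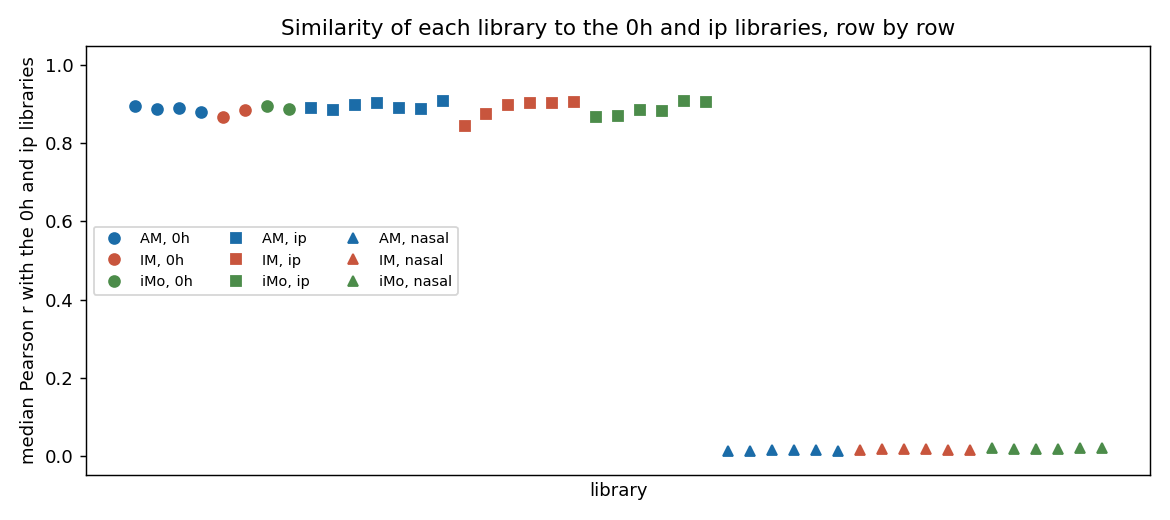
Each point is 1 library, and the vertical axis gives the median Pearson r of its log2(TPM+1) values with those of the 0h and ip libraries, row by row. The nasal libraries (triangles) lie near 0 and the 0h (circles) and ip libraries (squares) between 0.846 and 0.91.

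Before LPS, IM carried macrophage, monocyte and neutrophil transcripts that were low in AM. S100a9, a calcium-binding protein abundant in neutrophils and monocytes, was at 7944 ± 3939 TPM (SD, n = 2) in IM and at 9.9 ± 10.3 TPM (SD, n = 4) in AM, a log2 fold change of 9.91 (SE 0.69, adjusted p = 2.16e-10). C1qa, a complement subunit of tissue macrophages, had a log2 fold change of 9.12 (SE 1.0, adjusted p = 1.66e-07), and Plac8, Retnlg and Retnla were higher by 9.28, 9.32 and 8.97. Lower by the most were F7 (-5.28), Ear1 (-5.20), Cidec (-5.11), Siglecf (-5.05), a surface lectin of AM, and Plet1 (-5.04). Higher in IM were 15 of 16 interstitial macrophage markers (C1qc 8.78, Aif1 7.37), 9 of 10 classical monocyte markers (Ly6c2 8.36, Ms4a4c 7.28) and 6 of 7 nonclassical monocyte markers (Pou2f2 5.11, Adgre4 4.18). So were 22 of 23 type I interferon-stimulated genes (Irf7 5.86, Oasl2 5.17), 6 of 7 MHC class II genes (H2-Eb1 5.11, H2-Ab1 4.43), 10 of 12 immediate early genes against 1 that fell (Nr4a1 3.15, Egr1 3.15) and 10 of 17 chemokines against 2 that fell (Cxcl13 6.12, Ccl2 6.0). Markers of other cell types were higher in the same IM libraries: 7 of 10 neutrophil markers (S100a8 8.45, Cxcr2 4.75) and 9 of 9 endothelial markers (Cldn5 4.72, Ramp2 4.26). They included 6 of 7 lung epithelial markers against 1 that fell (Sftpc 3.43, Hopx 3.98), 6 of 6 lymphocyte markers (Cd79b 4.38, Gzma 3.56), 3 of 4 erythroid markers and Col3a1 (2.0), the 1 fibroblast marker tested. Lower in IM were 20 of 21 alveolar macrophage markers, 11 of 17 cell cycle genes (Ccnb2 -2.88, Bub1b -2.29) and 3 of 7 LXR and lipid efflux genes (Abcg1 -3.60, Nr1h3 -1.59). Adjusted over the list alone, the counts that differed were 23 higher among type I interferon-stimulated genes, 8 higher among neutrophil markers and 13 lower among cell cycle genes. Camera called interstitial macrophage markers, classical monocyte markers, immediate early genes, neutrophil markers and alveolar macrophage markers with both correlations. The other camera calls were lost with an estimated correlation, where the adjusted p was 0.0586 for nonclassical monocyte markers and type I interferon-stimulated genes, 0.161 for MHC class II genes and lung epithelial markers and 0.0819 for chemokines, endothelial markers and lymphocyte markers. The others had a p of 0.082 for cell cycle genes and 0.276 for LXR and lipid efflux genes. Camera made no call, with the preset correlation, at an adjusted p of 0.0514 for erythroid markers. No eosinophil marker was high enough to test. In all, limma called 2326 genes, 1344 higher and 982 lower in IM (median 0.005), and after quantile normalization 3493, of which 43% were higher, against 57.8%; after rescaling without Rn45s and Lars2 37.4% were (median -0.259), and without AM 0h N160623 49.9% of 2420. A neutrophil score as a covariate left 0 calls by limma (225 at an unadjusted p under 0.05) but raised the median SE from 0.38 to 1.58.

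Against AM, iMo at 0h were marked by monocyte and interferon-induced transcripts. Plac8 was at 5086 ± 1909 TPM (SD, n = 2) in iMo and 3.86 ± 3.39 TPM (SD, n = 4) in AM (log2 fold change 10.13, SE 0.65, adjusted p = 4.45e-11), and Ly6c2, the surface protein that defines this monocyte subset, at 3469 ± 2012.5 TPM (SD, n = 2) and 2.63 ± 1.92 TPM (SD, n = 4) (9.81, SE 0.70, adjusted p = 1.7e-10). Ifitm3, Ifitm6 and Ms4a4c were higher by 8.88, 8.70 and 8.39. Fabp1, a fatty acid binding protein, was at 309.7 ± 152 TPM (SD, n = 4) in AM and listed at 0 in iMo, and Plet1 (-7.79), Krt19 (-7.53), Atp6v0d2 (-7.44) and Cd9 (-7.34) were lower. Higher in iMo were 9 of 10 classical monocyte markers (F13a1 7.56, Plac8 10.13) and 23 of 23 type I interferon-stimulated genes (Irf7 6.08, Usp18 5.06). So were 11 of 13 interferon-gamma-associated genes against 1 that fell (Gbp3 4.38, Socs1 3.28) and 5 of 7 MHC class II genes (H2-Eb1 2.60, H2-Ab1 2.41). The iMo libraries lay apart in both lists, at log2 means of 4.1 and 6.32, and 7.05 and 8.91. Lower were 21 of 21 alveolar macrophage markers and 14 of 17 cell cycle genes (Ccnb2 -4.32, Bub1b -3.03). Also lower were 4 of 7 LXR and lipid efflux genes (Abcg1 -5.22, Nr1h3 -2.66) and 6 of 17 cholesterol synthesis genes (Dhcr7 -2.0, Mvd -1.59), and 2 of 10 neutrophil markers were higher. The counts adjusted over the list alone differed in 10 higher among classical monocyte markers, 16 lower among cell cycle genes and 5 lower among LXR and lipid efflux genes. With either correlation, camera called classical monocyte markers and alveolar macrophage markers. With an estimated correlation, camera gave an adjusted p of 0.104 for type I interferon-stimulated genes and 0.647 for interferon-gamma-associated genes, MHC class II genes and cholesterol synthesis genes, and these calls were lost. That p was also 0.0866 for cell cycle genes and 0.218 for LXR and lipid efflux genes. No camera call was made at an adjusted p of 0.241 for neutrophil markers. Limma called 2649 genes, 1448 higher and 1201 lower in iMo (median 0.147), and 1721 without the library iMo 0h B171227. After rescaling without Rn45s and Lars2, 30.2% of calls were higher, against 54.7% (median -0.277), and without AM 0h N160623 47.2% of 2444.

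Between iMo and IM at 0h, most calls were lower in iMo. S100a9 was at 9.17 ± 6.28 TPM (SD, n = 2) in iMo, a log2 fold change of -9.81 (SE 0.79, adjusted p = 1.04e-08) from IM, and C1qa at 2.45 ± 0.564 TPM (SD, n = 2) (-8.37, SE 1.16, adjusted p = 2.58e-05). Retnlg (-8.29) and Pf4 (-8.20) were lower, and Ccl8, a chemokine, was at 269 ± 54.8 TPM (SD, n = 2) in IM and listed at 0 in iMo. Prtn3, a serine protease of immature myeloid cells, was at 35.2 ± 6.96 TPM (SD, n = 2) in iMo and 5.29 ± 1.45 TPM (SD, n = 2) in IM (2.38, SE 0.42, adjusted p = 0.000173), and Vcan (2.25), Kcne3 (2.18), Dna2 (1.82) and Mrps18b (1.67) were higher. Lower in iMo were 10 of 16 interstitial macrophage markers (Folr2 -7.44, C1qa -8.37), 6 of 17 chemokines (Cxcl13 and Ccl12, both listed at 0 in iMo), 4 of 12 anti-inflammatory and feedback genes (Mrc1 -3.77, Cish -2.56) and 9 of 21 alveolar macrophage markers (Car4 -3.65, Krt19 -2.55). Lower with them were 6 of 10 neutrophil markers (S100a8 -7.45, Cxcr2 -5.56), 9 of 9 endothelial markers (Cldn5 -5.36, Egfl7 -5.05) and 5 of 7 lung epithelial markers (Sftpc -4.66, Sftpa1 -4.15). Of 10 classical monocyte markers, 1 was higher in iMo (Vcan). Counts that differed when adjusted over the list alone were 9 lower among chemokines and 6 lower among anti-inflammatory and feedback genes. Further ones were 1 higher and 17 lower among alveolar macrophage markers and 1 higher and 7 lower among neutrophil markers. The camera calls for chemokines, neutrophil markers, endothelial markers and lung epithelial markers held with both correlations. Lost with an estimated correlation were the calls at an adjusted p of 0.0546 for interstitial macrophage markers, 0.248 for anti-inflammatory and feedback genes and classical monocyte markers and 0.155 for alveolar macrophage markers. Limma called 631 genes, 66 higher and 565 lower in iMo (median 0.146), and 378 without iMo 0h A171227. Of the calls, 36.5% were higher after quantile normalization, 32.9% with array weights and 22.2% with the title code as a covariate, against 10.5%. Calls numbered 0 by limma (365 at an unadjusted p under 0.05) with a neutrophil score as a covariate, which raised the median SE.

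**Figure D2:**
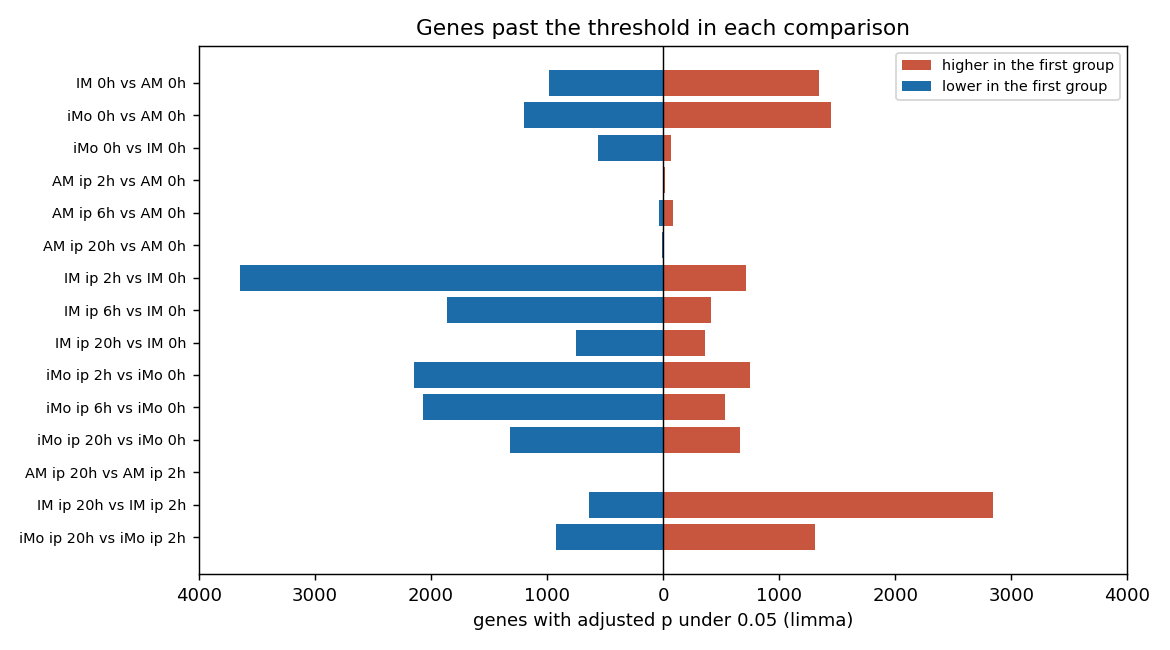
Bars give the number of genes with an adjusted p under 0.05 (limma) that were higher (right) or lower (left) in the first group named of each comparison. The AM comparisons with 0h hold 12, 116 and 10 genes.

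In AM at 2h of ip LPS, limma called few genes, with 2 libraries against 4 at 0h. Saa3, an acute-phase protein, went from 1.02 ± 0.882 TPM (SD, n = 4) to 45.5 ± 13.2 TPM (SD, n = 2), a log2 fold change of 4.64 (SE 0.67, adjusted p = 0.00178), and Lcn2, an iron-chelating lipocalin, from 2.01 ± 1.48 TPM (SD, n = 4) to 47.3 ± 18.3 TPM (SD, n = 2) (4.12, SE 0.56, adjusted p = 0.00159). Fkbp5, a glucocorticoid-induced chaperone, rose by 2.71. Single members of the lists rose: Rsad2 of 23 type I interferon-stimulated genes (3.03), Hp of 10 classical monocyte markers (2.48), Ier3 of 12 immediate early genes (1.99) and Socs3 of 12 anti-inflammatory and feedback genes (2.65). Limma called 0 of 10 neutrophil markers (5 at an unadjusted p under 0.05), 0 of 17 chemokines (7) and 0 of 9 endothelial markers (6), with mean log2 fold changes of 1.31, 0.85 and -1.17 and the largest values in S100a9 2.95, Cxcl10 3.53 and Tmem100 -2.08. When adjusted over the list alone, the counts that differed were 14 higher among type I interferon-stimulated genes, 3 higher among classical monocyte markers and 3 higher among anti-inflammatory and feedback genes. There were also 4 higher among neutrophil markers, 3 higher among chemokines and 4 lower among endothelial markers. Type I interferon-stimulated genes and neutrophil markers were called by camera with both correlations. Camera calls made with the preset correlation alone had an adjusted p of 0.195 for classical monocyte markers and 0.0903 for immediate early genes, anti-inflammatory and feedback genes, chemokines and endothelial markers with the estimated correlation. Limma called 12 genes, all higher (median -0.032), and 7 with the title code as a covariate. The list counts that the title code covariate moved over 1.5 times were 0 of the type I interferon-stimulated genes, classical monocyte markers and immediate early genes. After quantile normalization, 0 of the immediate early genes rose and 0 fell. Without AM 0h N160623 it called 14, of which 50% were higher. The gene count was 7 without AM 0h C171227, 0 without AM ip 2h N160623 and 4 without AM ip 2h B161219. A neutrophil score as a covariate left 0 calls by limma (235 at an unadjusted p under 0.05), with a larger median SE.

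At 6h of ip LPS, Saa3, Lcn2 and Hp and members of the monocyte, neutrophil and interferon lists were higher in the AM libraries than at 0h. Saa3 reached 463 ± 341 TPM (SD, n = 3), a log2 fold change of 7.81 (SE 0.59, adjusted p = 1.38e-08), and Lcn2 244 ± 74.2 TPM (SD, n = 3) (6.59, SE 0.50, adjusted p = 1.38e-08). Hp, which binds free haemoglobin, rose by 4.48 (SE 0.42), S100a9 by 4.52 and Ccl5, a T cell chemoattractant, by 4.43. Inmt (-2.82), Clec1b (-2.75), Clec7a (-2.41), the receptor of fungal glucans, Mgp (-2.29) and Tppp3 (-2.13) fell. Risers included 9 of 23 type I interferon-stimulated genes (Irf7 3.60, Isg15 2.89) and 5 of 10 classical monocyte markers (Plac8 3.73, Ly6c2 3.30). They also included 4 of 12 anti-inflammatory and feedback genes (Il1r2 3.45, Acod1 2.18), 3 of 12 immediate early genes (Ier3 2.34, Dusp1 2.23) and 2 of 17 chemokines (Ccl2 2.91), beside 4 of 10 neutrophil markers (S100a8 3.44, Retnlg 3.06). Fallers included 1 of 9 endothelial markers (Egfl7 -1.86) and 1 of 7 lung epithelial markers (Epcam -1.76), and limma called 0 of 7 MHC class II genes (2 at an unadjusted p under 0.05, mean -0.77, largest H2-Eb1 -1.28). Adjusted over the list alone, the counts that differed were 17 higher among type I interferon-stimulated genes and 4 higher among immediate early genes. Others were 6 higher among chemokines and 6 lower among endothelial markers. Camera called type I interferon-stimulated genes, classical monocyte markers, immediate early genes, chemokines and neutrophil markers with both correlations. The other camera calls were lost with an estimated correlation, where the adjusted p was 0.0691 for anti-inflammatory and feedback genes, 0.164 for endothelial markers and 0.633 for MHC class II genes. No camera call was made at an adjusted p of 0.0675 for lung epithelial markers. Limma called 116 genes, 83 higher and 33 lower (median -0.156); with the title code as a covariate the count was 15, all higher, and with array weights 1097, of which 34.9% were higher, against 71.6%. With the title code covariate, the list counts that moved over 1.5 times were 0 of the type I interferon-stimulated genes, anti-inflammatory and feedback genes, chemokines, endothelial markers and lung epithelial markers, 1 of the immediate early genes and 2 of the classical monocyte markers and neutrophil markers. Without AM 0h N160623 it called 159, of which 45.3% were higher. The gene count was 72 without AM 0h A171227, 49 without AM ip 6h A161219 and 52 without AM ip 6h B161219. Calls numbered 0 by limma (276 at an unadjusted p under 0.05) with a neutrophil score as a covariate, which raised the median SE. In the 2 IM libraries of 6h, Saa3 was at 24540 and 11860 TPM and S100a9 at 24860 and 7231 TPM. Which cells held these transcripts in the AM libraries was not tested.

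By 20h, Saa3 in AM was at 143 ± 165 TPM (SD, n = 2) (log2 fold change 5.80, SE 0.67, adjusted p = 0.000163) and Lcn2 at 55.1 ± 45.4 TPM (SD, n = 2) (4.38, SE 0.56, adjusted p = 0.000572). Rgs1, a regulator of G protein signalling, rose by 2.66, and Tppp3 (-2.97), Clec1b (-2.57) and Epcam (-2.36) fell. Of 10 neutrophil markers 1 rose, Ngp (3.01). Limma called 0 of 16 interstitial macrophage markers (10 at an unadjusted p under 0.05, mean 1.78, largest C1qb 4.01), 0 of 23 type I interferon-stimulated genes (5, mean 0.69, largest Irf7 1.73) and 0 of 17 cell cycle genes (4, mean 0.71, largest Rrm2 1.76). The AM ip 20h libraries stood apart from each other: A161219 held C1qb at 416 TPM and Apoe at 2933 TPM, and N160623 held them at 2.82 and 13.3 TPM. The counts adjusted over the list alone differed in 4 higher among neutrophil markers, 7 higher among interstitial macrophage markers and 2 higher among cell cycle genes. With either correlation, camera called neutrophil markers. With an estimated correlation, camera gave an adjusted p of 0.0505 for interstitial macrophage markers, 0.349 for type I interferon-stimulated genes and 0.0834 for cell cycle genes, and these calls were lost. Limma called 10 genes, 4 higher and 6 lower (median -0.31), and 3 with the title code as a covariate. Higher were 60.7% of 28 calls after quantile normalization and 76.9% of 26 after rescaling without Rn45s and Lars2, against 40%. Limma called 5 without AM 0h A171227, C171227 or D171227, 22 without AM 0h N160623, 207 (63.3% higher) without AM ip 20h N160623 and 1 without AM ip 20h A161219. A neutrophil score as a covariate left 0 calls by limma (296 at an unadjusted p under 0.05), with a larger median SE.

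In IM, ip LPS raised inflammatory transcripts within 2h. Saa3 went from 9.37 ± 0.96 TPM (SD, n = 2) to 7804 ± 2792.5 TPM (SD, n = 2) (log2 fold change 10.31, SE 0.77, adjusted p = 9.09e-09), Cxcl10, an interferon-induced chemokine, from 37.5 ± 43.2 TPM (SD, n = 2) to 7663 ± 4792 TPM (SD, n = 2) (8.99, SE 1.09, adjusted p = 4.06e-06), and Camp, an antimicrobial peptide of neutrophil granules, from a listed 0 to 251 ± 24.5 TPM (SD, n = 2). The largest falls were in Inmt (-6.15), Ramp2 (-6.14) and Gpihbp1 (-6.13), which endothelial cells express. Rising groups were 9 of 9 proinflammatory cytokines and enzymes (Il1a 6.21, Nos2 5.70, Tnf 5.34) and 10 of 17 chemokines against 2 that fell (Ccl3 8.04, Ccl4 7.39). Rising too were 13 of 16 NF-kB pathway and feedback genes (Tnfaip3 6.69, Tnip3 5.32), 21 of 23 type I interferon-stimulated genes (Rsad2 6.50, Ifit1 6.48) and 7 of 13 interferon-gamma-associated genes against 1 that fell (Gbp5 5.31, Cd274 3.95). Further risers were 9 of 12 anti-inflammatory and feedback genes against 2 that fell (Acod1 7.29, Il1rn 6.22) and 6 of 12 TLR4 pathway genes against 2 that fell (Cd14 4.26, Tlr2 3.59), and with them 5 of 10 neutrophil markers (Ngp 8.57, Ltf 5.91). Falling groups were 14 of 16 interstitial macrophage markers (Pf4 -5.12, Folr2 -4.75), 7 of 7 MHC class II genes (H2-DMb1 -3.99, H2-Eb1 -3.69) and 7 of 11 oxidative phosphorylation genes (Ndufb8 -1.65, Ndufa4 -1.34). With them fell 9 of 9 endothelial markers (Tmem100 -5.56, Egfl7 -5.33), 6 of 7 lung epithelial markers (Sftpc -4.21, Scgb1a1 -2.64), 5 of 6 lymphocyte markers (Cd79b -3.14, Ms4a1 -1.09) and 3 of 4 erythroid markers. Among 17 lineage transcription factors, Batf rose (4.91) and 7 fell (Batf3 -2.81). Of these counts, those that differed when adjusted over the list alone were 15 higher among NF-kB pathway and feedback genes, 15 lower among interstitial macrophage markers and 4 lower among erythroid markers. The camera calls for proinflammatory cytokines and enzymes, chemokines, NF-kB pathway and feedback genes, type I interferon-stimulated genes, anti-inflammatory and feedback genes and neutrophil markers held with both correlations. Lost with an estimated correlation were the calls at an adjusted p of 0.324 for interferon-gamma-associated genes and MHC class II genes, 0.29 for TLR4 pathway genes and 0.304 for interstitial macrophage markers. Further p-values were 0.227 for endothelial markers and 0.235 for lung epithelial markers. Camera made no call, with the preset correlation, at an adjusted p of 0.399 for oxidative phosphorylation genes, erythroid markers and lineage transcription factors and 0.212 for lymphocyte markers. Limma called 4356 genes, 714 higher and 3642 lower (median -0.795). With the title code as a covariate it called 1465, 36.9% of them higher, and after quantile normalization 48.5% were higher, against 16.4%. The list counts that the title code covariate moved over 1.5 times were 0 of the oxidative phosphorylation genes and erythroid markers, 1 of the lymphocyte markers, 2 of the interferon-gamma-associated genes, 3 of the lung epithelial markers and 4 of the lineage transcription factors. After quantile normalization, 0 of the erythroid markers rose and 0 fell.

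At 6h the IM libraries held Saa3 at 18201 ± 8961 TPM (SD, n = 2) (log2 fold change 11.22, SE 0.77, adjusted p = 2.1e-09) and Ngp, a neutrophil granule protein, at 880.4 ± 391 TPM (SD, n = 2) against 1.67 ± 0.504 TPM (SD, n = 2) at 0h (8.84, SE 0.56, adjusted p = 1.59e-09). Lcn2 rose by 6.90, Arg1, the arginase of alternatively activated macrophages, by 6.49, and Camp went from a listed 0 to 236 ± 135 TPM (SD, n = 2). Mgp (-7.06), Inmt (-6.58), Retnla (-6.0), a resistin-like protein, Gpihbp1 (-5.92) and Tspan7 (-5.81) fell. Higher than at 0h were 7 of 9 proinflammatory cytokines and enzymes (Il1a 4.93, Tnf 4.27) and 8 of 17 chemokines against 2 that fell (Ccl5 5.80, Ccl3 5.74). So were 8 of 16 NF-kB pathway and feedback genes against 1 that fell (Tnfaip3 4.32, Tnip1 3.30) and 17 of 23 type I interferon-stimulated genes (Isg15 4.54, Ifit1 4.05). Further ones were 9 of 12 anti-inflammatory and feedback genes against 1 that fell (Acod1 5.42, Il1rn 4.64), 4 of 12 glycolysis genes (Pfkfb3 3.90, Eno1 1.85) and 5 of 10 neutrophil markers (Ltf 5.60, Ngp 8.84). Lower were 12 of 16 interstitial macrophage markers (Folr2 -5.81, C1qa -4.78) and 7 of 7 MHC class II genes (H2-Eb1 -5.06, H2-Aa -4.68). Among markers of other cells, lower ones were 9 of 9 endothelial markers (Cldn5 -5.75, Tmem100 -5.66), 6 of 7 lung epithelial markers (Sftpc -5.03, Sftpa1 -2.76), 5 of 6 lymphocyte markers and 2 of 2 dendritic cell markers (Cd209a -3.54, Siglech -2.15). When adjusted over the list alone, the counts that differed were 10 higher among chemokines, 9 higher among NF-kB pathway and feedback genes and 19 higher among type I interferon-stimulated genes. Others were 13 lower among interstitial macrophage markers and 6 lower among lymphocyte markers. Proinflammatory cytokines and enzymes, anti-inflammatory and feedback genes and neutrophil markers were called by camera with both correlations. Camera calls made with the preset correlation alone had an adjusted p of 0.0508 for chemokines, 0.124 for NF-kB pathway and feedback genes, 0.0687 for type I interferon-stimulated genes, 0.0914 for glycolysis genes and 0.203 for interstitial macrophage markers with the estimated correlation. It was also 0.118 for MHC class II genes, 0.0784 for endothelial markers, 0.0899 for lung epithelial markers, 0.205 for lymphocyte markers and 0.0806 for dendritic cell markers. Limma called 2275 genes, 414 higher and 1861 lower (median -0.534); the title code covariate left 430, 40.7% of them higher, and after quantile normalization 51.8% were higher, against 18.2%; after rescaling without Rn45s and Lars2 31% were (median -0.267). With the title code covariate, the list counts that moved over 1.5 times were 0 of the lymphocyte markers, 1 of the lung epithelial markers, 2 of the glycolysis genes, 5 of the type I interferon-stimulated genes and endothelial markers and 7 of the interstitial macrophage markers. Limma called 1124 without IM 0h A171227, 1247 without IM 0h B171227 and 1213 without IM ip 6h N160623.

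At 20h, Saa3 in IM was at 7761 ± 1869 TPM (SD, n = 2) (log2 fold change 9.62, SE 0.77, adjusted p = 1.57e-08), Ngp at 561 ± 7.4 TPM (SD, n = 2) (7.82, SE 0.56, adjusted p = 2.1e-09) and Camp at 55 ± 33.8 TPM (SD, n = 2), up from a listed 0. Retnla fell from 2267 ± 1875 TPM (SD, n = 2) to 3.62 ± 3.28 TPM (SD, n = 2) (-8.76, SE 0.86, adjusted p = 2.43e-07), Inmt fell (-6.83), and Gpihbp1 was listed at 0. Proliferation genes rose, with 15 of 17 cell cycle genes (Mcm5 3.13, Rrm2 2.03), as did 8 of 12 anti-inflammatory and feedback genes against 1 that fell (Arg1 5.49, Hmox1 3.85). Also higher were 5 of 10 neutrophil markers (Ly6g 3.06, Ngp 7.82), 4 of 12 glycolysis genes (Pfkfb3 2.17, Eno1 1.42) and 2 of 9 proinflammatory cytokines and enzymes (Tnf 2.54, Nos2 1.74). Lower were 7 of 7 MHC class II genes (H2-Eb1 -5.50, H2-Aa -5.30) and 8 of 16 interstitial macrophage markers (Pf4 -5.82, Lyve1 -5.79). The same held for 2 of 2 dendritic cell markers (Cd209a -4.47), 6 of 6 lymphocyte markers (Gzma -3.47, Nkg7 -2.83), 9 of 9 endothelial markers (Cldn5 -5.82, Tmem100 -5.79) and 6 of 7 lung epithelial markers (Sftpc -4.97, Sftpa1 -3.03). Adjusted over the list alone, the counts that differed were 17 higher among cell cycle genes, 9 higher and 2 lower among anti-inflammatory and feedback genes and 6 higher among neutrophil markers. Further ones were 4 higher and 1 lower among proinflammatory cytokines and enzymes, 9 lower among interstitial macrophage markers and 7 lower among lung epithelial markers. Camera called cell cycle genes, neutrophil markers, dendritic cell markers, endothelial markers and lung epithelial markers with both correlations. The other camera calls were lost with an estimated correlation, where the adjusted p was 0.05 for anti-inflammatory and feedback genes and MHC class II genes and 0.222 for glycolysis genes and interstitial macrophage markers. The others had a p of 0.181 for proinflammatory cytokines and enzymes and 0.0647 for lymphocyte markers. Limma called 1112 genes, 362 higher and 750 lower (median -0.092); the covariate fit called 184 and quantile normalization 2220, 55.1% of them higher, against 32.6%; after rescaling without Rn45s and Lars2 58.2% were (median 0.142). List counts that moved over 1.5 times with the title code covariate were 0 of the glycolysis genes, lymphocyte markers and lung epithelial markers, 1 of the cell cycle genes, 3 of the anti-inflammatory and feedback genes and endothelial markers and 4 of the interstitial macrophage markers. The gene count was 642 without IM 0h A171227, 713 without IM 0h B171227, 669 without IM ip 20h A161219 and 656 without IM ip 20h B161219.

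In iMo, 2h of ip LPS raised Sdc4, a cell-surface proteoglycan, from 0.395 ± 0.205 TPM (SD, n = 2) to 512 ± 235 TPM (SD, n = 2) (log2 fold change 8.87, SE 0.64, adjusted p = 1.92e-09). The chemokine Ccl4 went from 4.96 ± 2.25 TPM (SD, n = 2) to 1649.8 ± 688 TPM (SD, n = 2) (8.53, SE 0.73, adjusted p = 3.61e-08) and Acod1, the enzyme that makes itaconate, from 1.14 ± 1.28 TPM (SD, n = 2) to 492.5 ± 246 TPM (SD, n = 2) (8.32, SE 0.58, adjusted p = 1.23e-09). Ypel3 (-5.28), Cdc42ep3 (-4.39) and Rp9 (-4.17) fell most. Members that rose were 7 of 9 proinflammatory cytokines and enzymes (Nos2 5.86, Il6 5.06) and 11 of 17 chemokines (Cxcl10 8.17, Ccl5 7.15). Others were 11 of 16 NF-kB pathway and feedback genes (Tnfaip3 6.54, Tnip3 5.92) and 20 of 23 type I interferon-stimulated genes (Rsad2 6.30, Isg15 5.57). Further risers were 7 of 12 anti-inflammatory and feedback genes (Il1rn 7.20, Acod1 8.32), 5 of 17 cell cycle genes (Top2a 1.97, Tpx2 1.75) and, beside them, 6 of 10 neutrophil markers (S100a9 3.47, Camp 3.92). Those that fell were 6 of 7 MHC class II genes (H2-Eb1 -3.77, H2-DMa -3.04), 6 of 11 oxidative phosphorylation genes (Cox6c -1.70, Ndufb8 -1.45) and 4 of 16 interstitial macrophage markers (Cx3cr1 -2.76, Aif1 -2.01). The counts adjusted over the list alone differed in 12 higher among NF-kB pathway and feedback genes and 8 higher among anti-inflammatory and feedback genes. There were also 7 lower among oxidative phosphorylation genes and 3 lower among interstitial macrophage markers. With either correlation, camera called proinflammatory cytokines and enzymes, chemokines and anti-inflammatory and feedback genes. With an estimated correlation, camera gave an adjusted p of 0.109 for NF-kB pathway and feedback genes, 0.0783 for type I interferon-stimulated genes and 0.476 for cell cycle genes, and these calls were lost. That p was also 0.197 for neutrophil markers and 0.524 for MHC class II genes. Camera made no call, with the preset correlation, at an adjusted p of 0.237 for oxidative phosphorylation genes and 0.867 for interstitial macrophage markers. Limma called 2897 genes, 752 higher and 2145 lower (median -0.425), and 594 with the title code as a covariate, 49.8% of them higher; after quantile normalization 49.5% were higher, against 26%; after rescaling without Rn45s and Lars2 48.3% were (median -0.026). The list counts that the title code covariate moved over 1.5 times were 0 of the cell cycle genes and oxidative phosphorylation genes, 3 of the neutrophil markers and MHC class II genes and 10 of the type I interferon-stimulated genes. Without iMo 0h A171227 it called 1911, without iMo 0h B171227 1705 and without iMo ip 2h B161219 1398. Calls numbered 1861 with a neutrophil score as a covariate, which raised the median SE.

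At 6h, Saa3 in iMo had gone from 35.8 ± 2.81 TPM (SD, n = 2) to 15885 ± 6341 TPM (SD, n = 2) (log2 fold change 9.18, SE 0.77, adjusted p = 8.45e-08) and Lcn2 from 23.3 ± 1.92 TPM (SD, n = 2) to 4851 ± 1262 TPM (SD, n = 2) (8.10, SE 0.65, adjusted p = 5.32e-08). Sdc4 (8.19) and AA467197 (7.43) rose, and Ngp went from a listed 0 to 229 ± 1.22 TPM (SD, n = 2). H2-Eb1 fell from 456 ± 504 TPM (SD, n = 2) to 4.41 ± 0.486 TPM (SD, n = 2) (-5.25, SE 0.84, adjusted p = 3.22e-05), and so did H2-Aa (-4.62), Clec7a (-4.66) and Cx3cr1 (-4.31), the fractalkine receptor, while Fcor went from 37.3 ± 21.5 TPM (SD, n = 2) to a listed 0. Cell cycle genes rose, 16 of 17 (Ccnb2 5.22, Cdc20 4.19, Birc5 3.54), with 7 of 10 neutrophil markers (Camp 7.25, S100a9 6.75) and 10 of 17 chemokines (Ccl5 6.69, Ccl12 from a listed 0, Ccl7 5.61). So did 8 of 12 anti-inflammatory and feedback genes (Acod1 7.04, Il1rn 5.86), 5 of 9 proinflammatory cytokines and enzymes (Nos2 3.28, Il6 3.22), 6 of 23 type I interferon-stimulated genes against 1 that fell (Isg15 3.41, Rsad2 3.14) and 2 of 17 cholesterol synthesis genes (Srebf2 2.82, Sqle 1.99). Falls covered 7 of 7 MHC class II genes and 3 of 10 classical monocyte markers against 1 that rose (S100a4 -2.26, Ccr2 -2.0). Counts that differed when adjusted over the list alone were 9 higher among anti-inflammatory and feedback genes and 5 lower among classical monocyte markers. The camera calls for cell cycle genes, neutrophil markers, chemokines, anti-inflammatory and feedback genes and proinflammatory cytokines and enzymes held with both correlations. Lost with an estimated correlation were the calls at an adjusted p of 0.656 for type I interferon-stimulated genes, 0.466 for cholesterol synthesis genes and 0.375 for MHC class II genes. No camera call was made at an adjusted p of 0.602 for classical monocyte markers. Limma called 2600 genes, 532 higher and 2068 lower (median -0.482), and 375 with the covariate (39.2% higher); quantile normalization put 48.5% of calls higher, against 20.5%, and rescaling without Rn45s and Lars2 62.3% (median 0.177). With the title code covariate, the list counts that moved over 1.5 times were 0 of the type I interferon-stimulated genes and cholesterol synthesis genes, 1 of the classical monocyte markers, 5 of the anti-inflammatory and feedback genes and 10 of the cell cycle genes. After quantile normalization or rescaling without Rn45s and Lars2, 1 of the classical monocyte markers rose and 1 fell. Without iMo 0h A171227 the count was 1543, without iMo 0h B171227 1405 and without iMo ip 6h B161219 1433. A neutrophil score as a covariate left 105 calls, with a larger median SE.

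At 20h, iMo held Saa3 at 6936 ± 1851 TPM (SD, n = 2) (log2 fold change 7.84, SE 0.77, adjusted p = 7.02e-07) and S100a9 at 1159 ± 52.6 TPM (SD, n = 2) against 9.17 ± 6.28 TPM (SD, n = 2) at 0h (7.30, SE 0.79, adjusted p = 2.64e-06). Ngp went from a listed 0 to 146 ± 46 TPM (SD, n = 2), Cd209a, a lectin of monocyte-derived dendritic cells, from 41.8 ± 30.3 TPM (SD, n = 2) to a listed 0, and Apoc1 (-4.26) and Mgst1 (-3.98) fell. Every tested cell cycle gene rose, 17 of 17 (Rrm2 4.47, Ccnb2 4.16, Mcm2 4.13), as did 8 of 10 neutrophil markers against 1 that fell (Retnlg 5.27, S100a9 7.30) and 8 of 17 chemokines (Ccl7 4.20, Ccl12 from a listed 0, Ccl4 3.79). Rising too were 6 of 12 anti-inflammatory and feedback genes (Acod1 6.0, Arg1 4.90) and 5 of 16 interstitial macrophage markers against 2 that fell (C1qa 6.51, C1qc 6.01). Of 21 alveolar macrophage markers, 3 rose, among them the scavenger receptor Marco (6.92), and 2 fell. Lower were 7 of 7 MHC class II genes (H2-Aa -3.42, H2-Ab1 -3.02), 7 of 10 classical monocyte markers (Ccr2 -3.48, Vcan -2.71) and 6 of 23 type I interferon-stimulated genes against 1 that rose (Xaf1 -1.44, Isg15 2.19). When adjusted over the list alone, the counts that differed were 5 higher among alveolar macrophage markers and 8 lower among type I interferon-stimulated genes. Cell cycle genes and neutrophil markers were called by camera with both correlations. Camera calls made with the preset correlation alone had an adjusted p of 0.191 for chemokines, 0.0603 for anti-inflammatory and feedback genes and 0.641 for interstitial macrophage markers with the estimated correlation. It was also 0.573 for alveolar macrophage markers and 0.349 for MHC class II genes and classical monocyte markers. Camera made no call for type I interferon-stimulated genes (adjusted p = 0.125). Limma called 1981 genes, 660 higher and 1321 lower (median -0.311); with the covariate it called 265 (54% higher), and after quantile normalization 51.4% were higher, against 33.3%; after rescaling without Rn45s and Lars2 80.4% were (median 0.337). List counts that moved over 1.5 times with the title code covariate were 0 of the interstitial macrophage markers and type I interferon-stimulated genes, 1 of the alveolar macrophage markers and MHC class II genes, 2 of the anti-inflammatory and feedback genes, 4 of the classical monocyte markers and 5 of the neutrophil markers and chemokines. After rescaling without Rn45s and Lars2, 2 of the type I interferon-stimulated genes rose and 2 fell. Limma called 981 without iMo 0h A171227, 865 without iMo 0h B171227, 1092 without iMo ip 20h A161219 and 760 without iMo ip 20h B161219. Calls numbered 14 with a neutrophil score as a covariate, which raised the median SE.

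**Figure D3:**
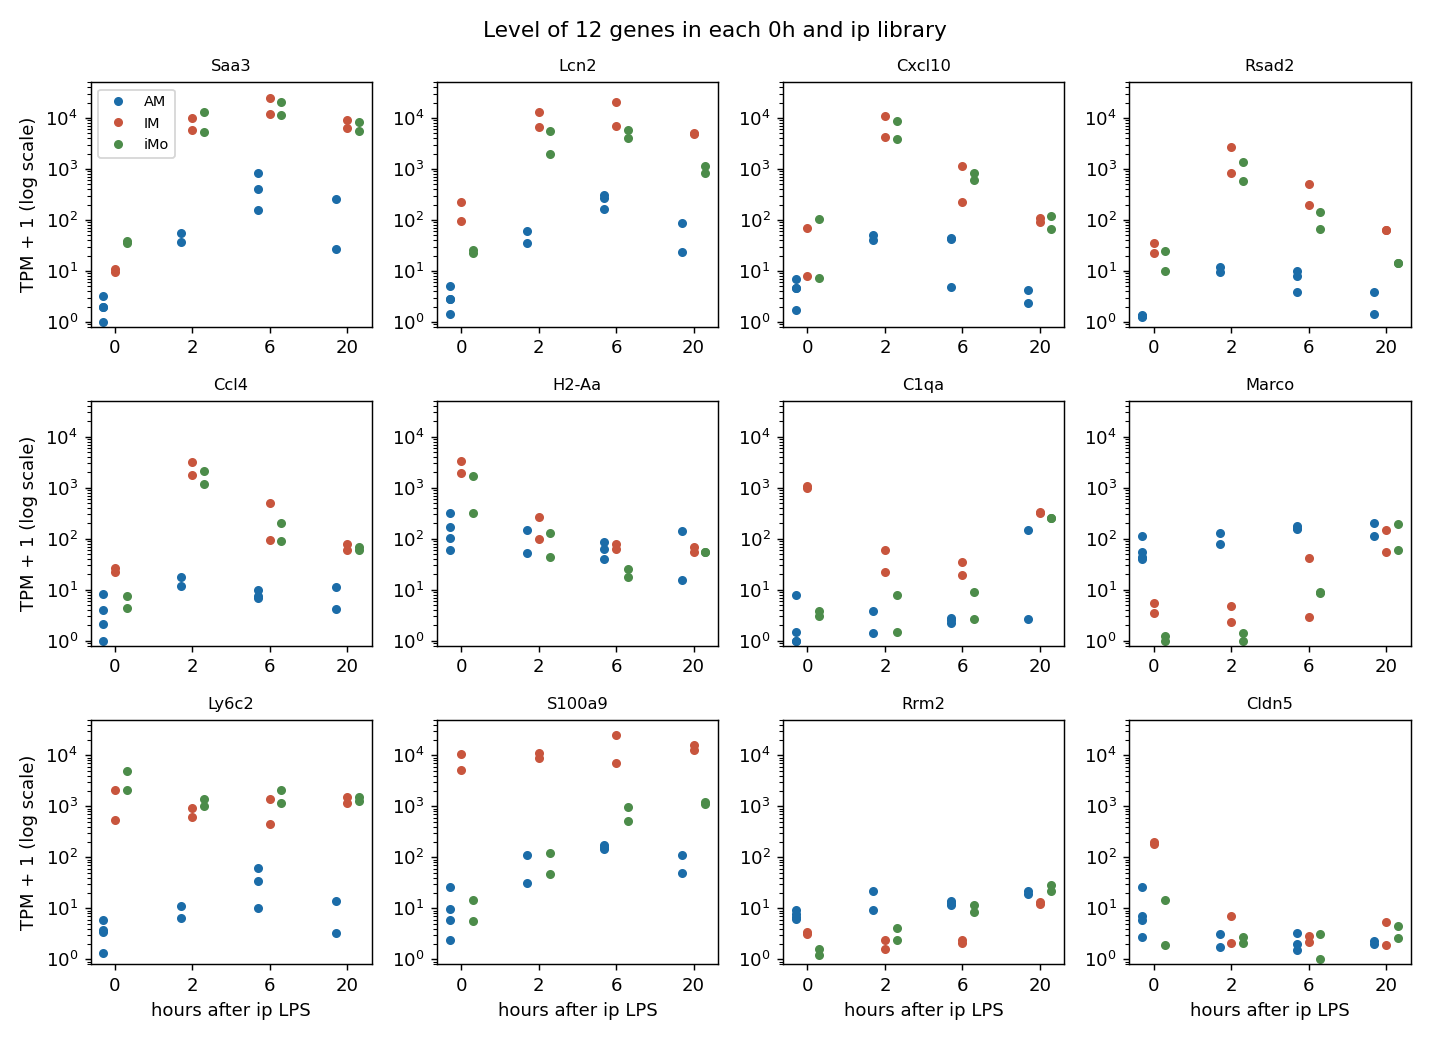
Each point is the level of 1 gene in 1 library as TPM + 1 on a log axis, against hours after ip LPS, for AM (blue), IM (red) and iMo (green). Saa3 was higher in the libraries of every cell type at 6h than at 0h, H2-Aa was lower in IM and iMo at each time than at 0h, and S100a9 was higher in IM than in iMo at each time.

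Within the ip course, whose libraries carry other title codes than those of IM at 0h, IM lost interferon and chemokine transcripts between 2h and 20h. Cxcl10 fell from 7663 ± 4792 TPM (SD, n = 2) to 99.3 ± 14.3 TPM (SD, n = 2) (log2 fold change -6.76, SE 1.09, adjusted p = 0.000218), and Cxcl11 (-6.66) and Thbs1, a matricellular protein (-6.04), fell. Marco rose from 2.49 ± 1.67 TPM (SD, n = 2) to 99.5 ± 64.4 TPM (SD, n = 2) (4.12, SE 0.78, adjusted p = 9.19e-05), and Lair1 (3.93) and Arg1 (3.82) rose. Lower at 20h were 20 of 23 type I interferon-stimulated genes (Rsad2 -5.21, Ifit1 -5.09) and 8 of 9 proinflammatory cytokines and enzymes (Il1a -4.58, Nos2 -3.91). So were 9 of 17 chemokines (Ccl4 -5.76, Cxcl10 -6.76) and 12 of 16 NF-kB pathway and feedback genes (Tnfaip3 -4.63, Tnip3 -4.39). Further falls were in 7 of 13 interferon-gamma-associated genes (Gbp5 -5.27, Socs1 -5.0) and 5 of 12 immediate early genes (Dusp1 -3.78, Atf3 -3.69). Higher were 16 of 17 cell cycle genes (Mcm5 2.36, Mcm2 2.28), 9 of 16 interstitial macrophage markers against 1 that fell (C1qb 3.52, C1qc 3.10) and 7 of 11 oxidative phosphorylation genes (Ndufb8 1.86, Cox5a 1.08), and 2 of 10 neutrophil markers against 1 that rose were lower (Camp -2.96, Ltf -2.32). Adjusted over the list alone, the counts that differed were 21 lower among type I interferon-stimulated genes and 10 lower among chemokines. There were also 13 lower among NF-kB pathway and feedback genes and 8 higher among oxidative phosphorylation genes. Camera called type I interferon-stimulated genes, proinflammatory cytokines and enzymes, chemokines and immediate early genes with both correlations. The other camera calls were lost with an estimated correlation, where the adjusted p was 0.0599 for NF-kB pathway and feedback genes, 0.183 for interferon-gamma-associated genes and 0.174 for cell cycle genes. Camera made no call, with the preset correlation, at an adjusted p of 0.284 for interstitial macrophage markers, 0.0666 for oxidative phosphorylation genes and 0.239 for neutrophil markers. Limma called 3487 genes, 2846 higher and 641 lower at 20h (median 0.649), and after quantile normalization 53.3% were higher, against 81.6%. The list counts that the title code covariate moved over 1.5 times were 1 of the neutrophil markers. After rescaling without Rn45s and Lars2, 2 of the neutrophil markers rose and 2 fell. The gene count was 2040 without IM ip 2h N160623 and 1661 without IM ip 20h B161219.

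In iMo over the same interval, C1qc rose from 2.57 ± 2.33 TPM (SD, n = 2) to 351 ± 52.4 TPM (SD, n = 2) (log2 fold change 6.65, SE 1.24, adjusted p = 0.000312), C1qa by 6.08 and Marco from 0.194 ± 0.274 TPM (SD, n = 2) to 127 ± 96.9 TPM (SD, n = 2) (6.38, SE 0.78, adjusted p = 2.44e-06). Thbs1 fell (-6.58), as did Cxcl10, from 6328 ± 3488.5 TPM (SD, n = 2) to 91.7 ± 37.3 TPM (SD, n = 2) (-6.17, SE 1.09, adjusted p = 0.000286), and Cxcl11 went from 87.7 ± 48.4 TPM (SD, n = 2) to a listed 0. Lower at 20h were 22 of 23 type I interferon-stimulated genes (Rsad2 -6.15, Ifit1 -5.59), 11 of 16 NF-kB pathway and feedback genes (Tnfaip3 -4.33, Tnip3 -4.09) and 6 of 9 proinflammatory cytokines and enzymes (Nos2 -5.13, Il6 -3.46). So were 7 of 17 chemokines (Ccl4 -4.76, Cxcl10 -6.17), 6 of 10 classical monocyte markers (Vcan -4.13, Hp -3.88) and 6 of 12 TLR4 pathway genes against 1 that rose (Cd14 -2.83, Myd88 -1.68). Higher were 16 of 17 cell cycle genes (Mcm6 3.45, Mcm5 3.31), 7 of 16 interstitial macrophage markers (Folr2 2.75, C1qc 6.65) and, beside them, 7 of 10 neutrophil markers against 1 that fell (Retnlg 4.77, S100a9 3.80). The counts adjusted over the list alone differed in 7 lower among TLR4 pathway genes and 17 higher among cell cycle genes. With an estimated correlation, camera gave an adjusted p of 0.0612 for type I interferon-stimulated genes, proinflammatory cytokines and enzymes and cell cycle genes, 0.245 for NF-kB pathway and feedback genes and classical monocyte markers and 0.139 for chemokines, and these calls were lost. That p was also 0.486 for TLR4 pathway genes, 0.651 for interstitial macrophage markers and 0.35 for neutrophil markers. Limma called 2230 genes, 1310 higher and 920 lower at 20h (median 0.139); after rescaling without Rn45s and Lars2 75.3% were higher, against 58.7% (median 0.422). With no filter 39.2% were higher. The gene count was 890 (45.6% higher) without iMo ip 2h B161219, 1216 without iMo ip 20h A161219 and 1300 without iMo ip 20h B161219. A neutrophil score as a covariate left 495 calls, with a larger median SE.

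In AM, 2 genes differed between 20h and 2h (median -0.275): Tppp3 fell from 216 ± 116 TPM (SD, n = 2) to 27.1 ± 3.28 TPM (SD, n = 2) (-2.57, SE 0.47, adjusted p = 0.017) and Socs3, a cytokine signalling inhibitor, from 36 ± 14 TPM (SD, n = 2) to 4.57 ± 1.54 TPM (SD, n = 2) (-2.43, SE 0.45, adjusted p = 0.017). Limma called 0 of 23 type I interferon-stimulated genes (8 at an unadjusted p under 0.05, mean -0.60, largest Rsad2 -1.89) and 0 of 16 interstitial macrophage markers (5, mean 1.67, largest C1qb 4.65). The counts adjusted over the list alone were 4 lower among type I interferon-stimulated genes and 2 higher among interstitial macrophage markers. With an estimated correlation, camera gave an adjusted p of 0.907 for type I interferon-stimulated genes and 0.1 for interstitial macrophage markers, and these calls were lost. The gene count was 4 with the title code as a covariate, 0 without AM ip 2h B161219, 88 (89.8% higher) without AM ip 20h N160623 and 0 without AM ip 20h A161219.

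**Figure D4:**
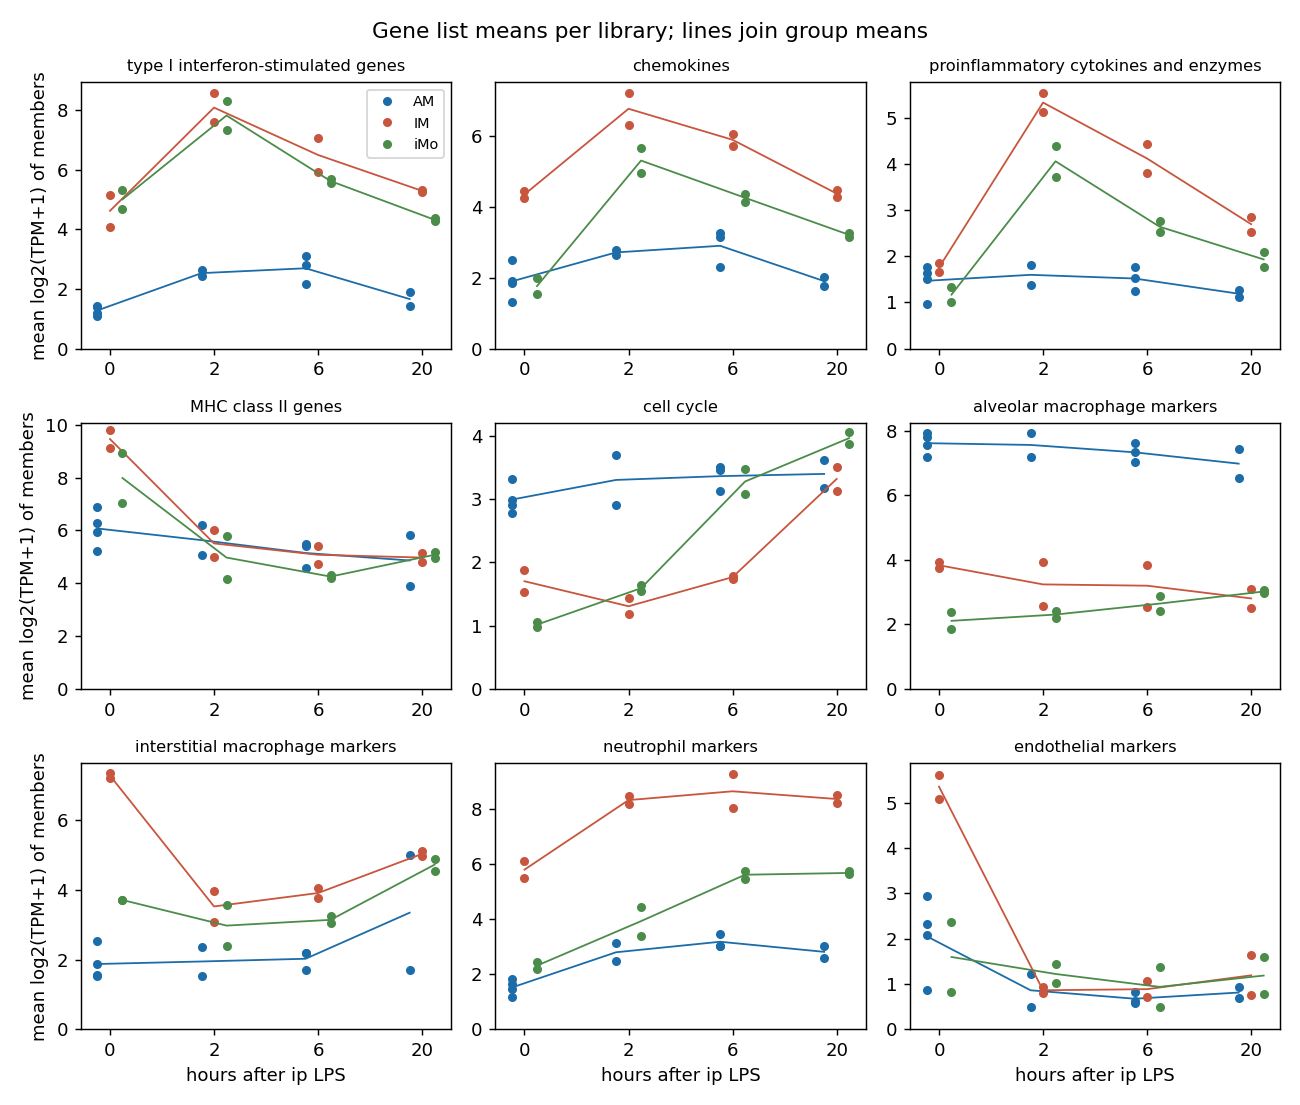
Each point is the mean log2(TPM+1) of the tested members of 1 list in 1 library, against hours after ip LPS, for AM (blue), IM (red) and iMo (green), with lines through the group means. Interferon-stimulated genes were highest at 2h in IM and iMo, cell cycle means were highest at 20h in both, and the endothelial mean of IM was highest at 0h.

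Differences of the ip response between cell types were tested with limma's moderated F test over the 3 times. Responses of IM and AM differed for 2368 genes, of which the C-type lectins Mgl2 (F = 72.6, adjusted p = 4.05e-08), Cd209g and Cd209f, the Fc receptor-like Fcrls and the sulfotransferase Sult1a1 fell more in IM, and Gpr84, a receptor of medium-chain fatty acids, rose more; Gpr84 differed by 5.54, 4.16 and 5.07 on the log2 scale at 2, 6 and 20h and Mgl2 by -5.23, -5.57 and -7.04. Responses of iMo and AM differed for 1550 genes: Ccnb2 (F = 42.9, adjusted p = 3.75e-06) by 0.73, 5.14 and 4.46, and the interleukin-1 receptor antagonist Il1rn by 7.17, 5.7 and 1.45, followed by AA467197, Edn1, Ptges and Cryba4. Responses of iMo and IM differed for 335 genes, led by Cd209f (F = 51.1, adjusted p = 1.58e-06), at 54.6 ± 4.03 TPM (SD, n = 2) in IM at 0h and listed at 0 in iMo, with Cd209g, Mgl2, Ccl8, Fcrls and Cd163, a haemoglobin scavenger receptor that was at 21.9 ± 5.36 TPM (SD, n = 2) in IM at 0h and differed by 4.36, 3.8 and 2.75. These differences are not relative to the median of all genes. Cd209f and Ccl8, listed at 0 in iMo at 0h, could not fall there, so their differences also reflect the levels at 0h. So do those of any gene low at 0h in the cell type that fell less. With the title code as a covariate, 2338 genes differed between iMo and AM, and with a pseudocount of 0.1 the 335 of iMo and IM became 81. The counts for IM and AM were 1324 without AM ip 2h B161219, those for iMo and AM 891 without iMo 0h B171227 and 985 without iMo ip 2h B161219, and those for iMo and IM 210, 219 and 111 without IM 0h A171227, IM 0h B171227 and iMo 0h A171227.

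In the mm10 assembly with the GENCODE M21 annotation, Saa3 lies on chromosome 7 at 46711998 to 46715700, Lcn2 on chromosome 2 at 32384633 to 32388252 and Cxcl10 on chromosome 5 at 92346638 to 92348889. S100a8 (90668978 to 90670035) and S100a9 (90692632 to 90695721) lie on chromosome 3, and Retnlg lies on chromosome 16 at 48872621 to 48874496. Rsad2 is on chromosome 12 at 26442746 to 26456452, Ly6c2 on chromosome 15 at 75108158 to 75111970, C1qa on chromosome 4 at 136895917 to 136898803 and H2-Aa on chromosome 17 at 34282744 to 34287823. Marco is on chromosome 1 at 120474538 to 120505024 and Siglecf on chromosome 7 at 43351341 to 43359531. All 12 are annotated as protein-coding, and a TPM value covers a whole gene.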

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

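Chosen after their results were seen were the tests of the title code, the share of Rn45s and Lars2 and a common code shift. So were those of the monocyte count with the covariate and without 1 library. Those of neutrophils in the IM sort, monocytes in the IM gate and other AM splits were set before.

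Among the 4 AM libraries of 0h, 4 of 30 values had 1 library far from the others, measured as its gap to the nearest library over the range of the group; chance gives about 1 in 20. The ratios were 0.892 for dendritic cell markers in D171227, 0.873 for anti-inflammatory and feedback genes, 0.88 for TLR4 pathway genes and 0.873 for the Lars2 share of the column sum, these 3 in N160623, the library of another title code.

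By limma's F test, ip responses differed in 2368 genes for IM and AM, 1550 for iMo and AM and 335 for iMo and IM. In the nasal columns, whose row names did not match, 14 of 9006 rows differed between 20h and 2h in AM. In IM 1480 did (163 higher and 1317 lower at 20h) and in iMo 271 (62 higher and 209 lower).

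The first pattern weighed is that neutrophil transcripts such as S100a8 were higher in the IM than in the iMo libraries at 0h. Neutrophils in the IM sort may account for it: of 26 tested genes on another neutrophil list, 14 (53.8%) were higher in IM, against 6.3% of all tested genes, and 13 of 25 (52%) without Lcn2, whose values had been seen. Of this list 11 genes were at 5 TPM or more in iMo too and 11 in AM, so that it is not made up of neutrophil transcripts alone. Transcription of these genes by IM themselves was not tested and stays open.

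The second is the fall of interstitial macrophage markers and MHC class II genes in IM after ip LPS. Monocytes in the IM gate after LPS cannot be told apart from a response of IM: iMo and IM differed in 631 genes at 0h and in 219, 287 and 112 at 2, 6 and 20h, the highest being 45.5% of the 0h count, but 53.9% with the title code as a covariate (459 of 852); without 1 of the 2 iMo libraries they differed in 378 and 538 at 0h and 84 and 343 at 2h, and at an unadjusted p under 0.05 the counts were 1467, 1717, 1243 and 628. A code difference common to the cell types is argued against as the whole cause for 9 members. These were at 5 TPM or more in AM at 0h, and 7 were still lower at 2h with the code as a covariate. In the 8 AM libraries of the ip codes, mostly after LPS, their mean log2 level lay 0.88 (SD 0.77) below the other 3. In IM it fell by 4.02. In log2 fold changes that, like the 4.02, are not relative to the median of all genes (-0.795, and -0.373 with the covariate), Cd74 lost the call as its change shrank from -2.72 (SE 0.87) to -1.92 (SE 0.81), and Trem2 as its SE grew (-2.8, SE 0.71, to -2.78, SE 1.01). For the other 12, of which 10 were still lower, code and LPS cannot be told apart. The AM libraries that tie the codes hold them below 5 TPM. A code difference peculiar to IM and a response of IM to LPS, which the design names, stay open for all 21. So does a change of other cells in the sort: at 2h 9 of 9 endothelial markers fell and 5 of 10 neutrophil markers rose.

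The third is that more genes fell than rose in IM and iMo after ip LPS, which depended on the setting (see also the alternatives): it did not hold after rescaling without Rn45s and Lars2 in IM at 20h (58.2% of calls higher) or in iMo at 6h (62.3%) and 20h (80.4%), nor in iMo at 20h with the title code as a covariate (54%), and quantile normalization evened it out (48.5 to 55.1%). The share of Rn45s and Lars2 may account for it in iMo at 2h. Rescaling moved the median of all genes from -0.425 to -0.03, although the 2 libraries lay at 0.19 and -0.25. In IM at 2h this share alone is excluded, since the median stayed at -0.59 (libraries at -0.58 and -0.57). A code shift common to the cell types is argued against as the whole cause in IM at 2h, and elsewhere stays open. The 8 AM libraries of the ip codes lay at a mean of 0.1 (SD 0.06, from 0 to 0.17) on that scale. All but AM 0h N160623 (0.13) also had LPS. A code shift peculiar to IM, and a response to LPS, stay open. In IM, 4068 and 5374 genes had at least 5 TPM at 2h and 6895 and 6905 at 0h. Effects of this, or of the TPM share of induced genes, were not tested.

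For AM at 6h, 35 splits of the 7 libraries were too few to exclude chance. The real one gave 116 genes and the highest of the others 59. That split sets AM 0h A171227, C171227 and D171227 against the rest and so follows the title code. With the code as a covariate, 15 genes were called.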

How the results depend on the processing

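Settings chosen after the results were seen are named above. The planned nasal contrasts were not run. Nasal rows that differ between times were counted in a fit of those columns alone. Depth could not be varied in TPM. The fit with all 45 libraries takes part of its variance from the nasal columns, and the fit without code N160623 leaves 1 library in AM at 2h and 20h and in IM at 2h and 6h, so neither is a check of stability there. Without these 2 fits, 177 of 284 values of 18 gene counts lay within 1.5 times the reported count. Of 1358 values of 194 called lists, 1262 kept direction and call, 95 lost the call and 1 reversed; of 3926 values of 336 changes of named genes, 3584 kept both, 336 lost the call, 6 gained one and 0 reversed. Lists, called with the preset correlation, were not retested without 1 library, after rescaling or with the neutrophil score. With the title code of IM 0h alone, the 3 counts of the 0h pairs stayed within 1.5 times. Where not stated, the cause of moves below was not tested.

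AM counts after ip LPS (12, 116 and 10 at 2, 6 and 20h) moved in most settings. They were 43 at 2h with a pseudocount of 0.1; 67 at 6h and 4 at 20h with no filter, where more genes were tested; 20, 256 and 28 after quantile normalization; 0 at 2h and 1097 at 6h with array weights; 7, 15 and 3 with the title code as a covariate; 3 at 20h in the fit within AM; 19, 176 and 26 with all 45 libraries; 240 at 6h and 1706 at 20h (1 library) without code N160623; and 24, 253 and 26 after rescaling. The 2 genes of AM at 20h against 2h became 0 with array weights and in the fit within AM, 4 with the covariate and with all 45 libraries, and 1054 without code N160623, where 1 library is set against 1.

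For IM after ip LPS, the covariate gave 1465, 430 and 184 genes at 2, 6 and 20h, and the 1112 at 20h became 2220 after quantile normalization, 2299 with array weights, 1828 without code N160623 and 1778 after rescaling. For iMo the covariate gave 594, 375 and 265, and the 1981 at 20h became 3832 with array weights and 3148 without code N160623; at 20h against 2h rescaling gave 3562. At 0h, IM and AM differed in 3493 genes after quantile normalization, and iMo and IM in 975 with no filter, 1254 with array weights and 955 without code N160623. The F test of iMo and AM gave 1018 genes with no filter, 2338 with the covariate, 3125 without code N160623 and 2451 after rescaling. That of iMo and IM gave 81 with a pseudocount of 0.1, 503 after quantile normalization, 591 with array weights, 609 with all 45 libraries, 532 without code N160623 and 528 after rescaling. Medians of all genes after rescaling are given above.

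With the neutrophil score, IM against AM and iMo against IM at 0h gave 0 genes, AM after ip LPS 0 at each time, iMo after ip LPS 1861, 105 and 14, iMo at 20h against 2h 495, and the F tests of IM and AM 1435 and of iMo and IM 100. The SE grew by more than the changes moved: over the genes called without the score, the median size went from 1.79 to 1.28 and the median SE from 0.38 to 1.58 for IM against AM, from 2.32 to 2.41 and 0.44 to 1.46 for iMo against IM, from 1.87 to 1.43 and 0.36 to 0.71 for AM at 6h and from 1.58 to 1.83 and 0.42 to 1 for iMo at 20h.

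Of 18 pairs of groups, 9 had deviations correlated above 0.1 (from -0.245 to 0.549, median 0.107). The title codes go with shared deviations, at 0.115 to 0.549 in the 7 pairs whose libraries differ in code, and whether the letters pair libraries stays open, at 0.097 to 0.308 in 3 pairs of the same code and time and -0.245 to 0.099 in 8 of the same code across times. As a replicate block letters and codes gave 1401 genes for IM against AM and 1437 for iMo against AM at 0h. After ip LPS they gave 5, 24 and 3 for AM, 677, 149 and 47 for IM and 218, 147 and 114 for iMo. The F test of IM and AM gave 1316. The mean of the interstitial macrophage markers in iMo at 20h was 0.34, with the test reversed.

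Leaving out 1 library at a time gave 1650 to 2420 genes for IM against AM, 1721 to 2698 for iMo against AM and 378 to 538 for iMo against IM at 0h. After ip LPS the ranges at 2, 6 and 20h were 0 to 14, 49 to 159 and 1 to 207 in AM, 2974 to 4338, 1124 to 1526 and 642 to 713 in IM, and 1398 to 2589, 1405 to 2093 and 760 to 1092 in iMo. At 20h against 2h they were 0 to 88 in AM, 1661 to 3537 in IM and 890 to 2173 in iMo, and for the F tests 1324 to 3218 (IM and AM), 891 to 1979 (iMo and AM) and 111 to 427 (iMo and IM).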

Other observations

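At 2h and 6h of ip LPS, limma called neutrophil, immediate early, cytokine and chemokine transcripts higher in IM than in iMo libraries of the same time, and at 20h 7 of 10 neutrophil markers. These pairs, and the 6h against 2h contrasts below, were not planned and were tested in the same limma fit after seeing the data. Fold changes here are not relative to the median of all genes (0.401 at 2h, 0.104 at 6h and -0.091 at 20h). At 2h, Retnlg, a resistin-like protein of neutrophils, was at 1.82 TPM in iMo and 876.7 TPM in IM (means, n = 2 each; log2 fold change -8.3, SE 0.66, adjusted p = 1.97e-08), and Cxcl2, a chemokine that attracts neutrophils, at 11.7 and 834.5 TPM (-6.14, SE 0.61, adjusted p = 4.95e-07). Higher in IM at 2h were 8 of 10 neutrophil markers (S100a9 -7.02), 7 of 12 immediate early genes (Egr1, Junb, Nr4a1), 4 of 9 proinflammatory cytokines and enzymes (Tnf, Il1a, Il23a, Ptgs2) and 6 of 17 chemokines (Ccl3, Cxcl1). At 6h these counts were 7, 4, 4 and 6, and at 20h the neutrophil markers higher in IM included Cxcr2 (-3.78) and Ly6g (-3.73). At 20h limma called 0 of 12 immediate early genes (4 at an unadjusted p under 0.05), 0 of 9 proinflammatory cytokines and enzymes (4) and 1 of 17 chemokines, Cxcl13. At 2h and 6h the title codes differ, since 1 of the 2 IM libraries is N160623 and both iMo libraries carry the other ip code. With the code as a covariate the 4 counts were 9, 7, 5 and 4 at 2h and 7, 5, 5 and 6 at 6h. Without IM ip 2h A161219 they were 7, 1, 2 and 2, without iMo ip 2h A161219 7, 2, 2 and 3, without IM ip 6h A161219 4, 0, 1 and 5 and without iMo ip 6h B161219 4, 0, 2 and 4; without the N160623 library they were 8, 4, 3 and 3 at 2h and 7, 3, 5 and 5 at 6h.

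Higher in iMo at 6h were 8 of 17 cell cycle genes (9 with the covariate, 5 without iMo ip 6h B161219), and by name Hist1h2bb (33.8 against 1.49 TPM; log2 fold change 3.82, SE 0.57, adjusted p = 0.000184) and Hist1h1b (3.21), and Elane, the neutrophil elastase that immature myeloid cells transcribe (3.31, SE 0.49, adjusted p = 0.000184). Gzma, a granzyme of cytotoxic lymphocytes, was higher in iMo at 20h (37.4 against 2.88 TPM; 3.64, SE 0.65, adjusted p = 0.00235), with Elane (2.09). In all, limma called 219 genes at 2h (79 higher in iMo), 287 at 6h (82 higher) and 112 at 20h (4 higher), and with the title code as a covariate 322, 459 and 165. Without 1 library the counts were 61 (IM ip 2h A161219) to 343 (iMo ip 2h B161219) at 2h, 95 (iMo ip 6h B161219) to 235 (IM ip 6h N160623) at 6h and 39 (iMo ip 20h A161219) to 55 (iMo ip 20h B161219) at 20h. Of the interstitial macrophage, classical monocyte and MHC class II lists, limma called 0 members at each of the 3 times; at an unadjusted p under 0.05 these were 4, 4 and 1 at 2h, 3, 3 and 1 at 6h, and 1, 2 and 0 at 20h.

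Between 2h and 6h of ip LPS, limma called 644 genes in IM, 726 in iMo and 0 in AM (110 at an unadjusted p under 0.05). In the AM ip 20h library A161219, Trem2 was at 313 TPM and Arg1 at 59.8 TPM, against 31.3 and 0.313 TPM in N160623.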
